A study of Oryza sativa with 2 samples.

How the data were processed

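Small RNA was measured by sequencing in 2 libraries from rice (Oryza sativa, line SARII-658), 1 from diploid and 1 from autotriploid plants. An autotriploid carries 3 copies of a single genome where a diploid carries 2. Per the labels' protocols, the plants came from twin seedlings, the tissue was the middle of the fully extended flag leaf, and RNA from 3 biological replicates was mixed in equal amounts before each library was made. Per the labels' protocols, sequencing used an Illumina Genome Analyzer. The pooling leaves 1 library per ploidy, so no spread between plants could be measured.

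The deposited files hold single reads as sequences, 1 record per read, numbered by distinct sequence and copy. How adapters were removed, how reads were filtered and which size fraction was taken is not given in the sources used here. All deposited reads were 18 to 30 nt long and held no base other than A, C, G and T. A table of counts had been assumed when the tests were planned, so identical reads were tallied here to give a read count per distinct sequence. The diploid library held 7110496 reads and the autotriploid library 6197730 reads. Reads carried no molecular identifiers, so copies made by PCR cannot be told from separate molecules, and all intervals cover counting error only.

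Abundance was expressed as RPM, reads per 1000000 deposited reads of the library. A difference is given as the ratio of the autotriploid to the diploid library, with an exact conditional-binomial (Clopper-Pearson) 95% interval. Shares have exact binomial (Clopper-Pearson) 95% intervals and abundances exact Poisson 95% intervals. With 1 library per ploidy there is no test of ploidy and no p-value is given: every ratio compares these 2 libraries and has no replicate check. A feature was called 2-fold higher or lower where its ratio was at least 2 or at most 0.5 and its interval excluded 1. Where no read was found, 3 reads were taken as the upper limit, a one-sided 95% bound used in place of the two-sided Poisson interval. This limit is 0.422 RPM in the diploid and 0.484 in the autotriploid library.

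Because a class of small RNA can take reads from another, each ratio was also computed relative to the reads of 20 to 22 nt and with a trimmed-mean factor in the manner of TMM. The latter used sequences with 10 or more reads in both libraries, with 30% of log ratios and 5% of mean abundances trimmed from each end. Relative to the main scaling, these moved every log2 ratio by 0.26 and by -0.08. A direction is stated only where the interval lay on the same side of 1 under all 3 scalings, unless the text says otherwise.

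Lists of 85 mature sequences from 39 families of miRNA and tasiRNA were fixed before the data were examined, as were the comparisons, thresholds and naming rule. The lists were grouped by known targets or pathway, by occurrence in grasses, by a length of 24 nt or as panicle markers. They were written from general knowledge of rice and were not matched to a genome, so a family name stands for sequence identity and not for a locus. The 7 star sequences, for the complementary strands of miRNA duplexes, were written in the same way. A read was assigned to a family where its first 18 nt equalled those of a listed sequence. Families with 10 or more reads in at least 1 library were compared. Named are the families with 100 or more reads over both libraries and those called, the 10 most abundant unlisted sequences, and the 5 highest and 5 lowest ratios among unlisted sequences with 1000 or more reads. Single members of a family and named families below these limits were picked after their values were seen. The median log2 ratio of a list was set beside 10000 random lists of as many unlisted sequences of 20 to 22 nt, each drawn from the 50 nearest in mean abundance and seen in both libraries. The most abundant families have no unlisted sequence of like abundance, so their matches were less abundant. Because 24-nt and shorter sequences differed in their ratios, random lists matched also on the length class (20 to 22 or 23 to 24 nt) that held most of a family's reads were added after the data were seen. The percentile does not depend on the scaling, which moves both medians alike. In both kinds of random list the unlisted sequences included forms of listed families with shifted starts. A percentile therefore does not compare a list only with RNA outside the listed families.

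Alternatives to the scaling, the assignment, the read minimum, the length range and the unit counted were tried, and their effect is given at the close. Distinct sequences were compared after computing the number expected when the diploid library is thinned to the depth of the autotriploid one. The ratio call was checked on simulated libraries with the 4449 sequences that had 100 or more reads, 200 of them changed, 50 per fold size. Of the sequences simulated at 3-fold, 0.33-fold and 4-fold, 100%, 98% and 100% were called in the right direction. At 1.5-fold 2% passed the 2-fold limit, none of the unchanged sequences did, and the intervals covered the true ratio for 95% of sequences. The simulated libraries differed by counting error only, the model that the intervals assume. The check therefore covers the calculation and gives no rate of false calls from differences between plants, library preparation or PCR. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with Matplotlib 3.10.9 for plots. Planned counts by genome class, chromosome and genomic window needed a rice genome and were not analysed here, so no coordinates are given.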

Results

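Small RNAs of the rice flag leaf were compared between a diploid and an autotriploid library, each made from the pooled RNA of 3 biological replicates. The labels frame the study as a comparison of small RNA profiles between these ploidy levels. The diploid library held 7110496 reads of 2196941 distinct sequences, and the autotriploid library 6197730 reads of 2298182 distinct sequences. In the diploid library 80.9% of distinct sequences were seen once, against 81.7% in the autotriploid library. Of the 3958510 sequences found in either library, 536613 (13.6%) were found in both, and these carried 74.0% of diploid and 68.6% of autotriploid reads. With 1 library per ploidy there are no replicates, so ratios and intervals below describe these libraries and not the spread between plants.

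The first comparison asked how the size classes of small RNA differed. Plant miRNAs are mostly 21 or 22 nt long, and most siRNAs that guide DNA methylation are 24 nt long. Reads of 24 nt made up 44.9% of the autotriploid library (95% interval 44.85 to 44.93%) and 37.0% of the diploid library (36.92 to 36.99%), a difference of 7.94 percentage points. Reads of 23 nt were also more frequent, at 7.42% against 6.27%. Reads of 21 nt took 26.2% of the autotriploid and 31.8% of the diploid library, and reads of 22 nt took 12.9% and 15.0%. The longest reads were scarcer in the autotriploid library, with a ratio of 0.69 (0.68 to 0.70) at 28 nt and 0.50 (0.49 to 0.51) at 29 nt. Among distinct sequences the 24-nt class took 59.3% in the diploid and 62.3% in the autotriploid library, a difference of 2.99 percentage points.

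**Figure D1:**
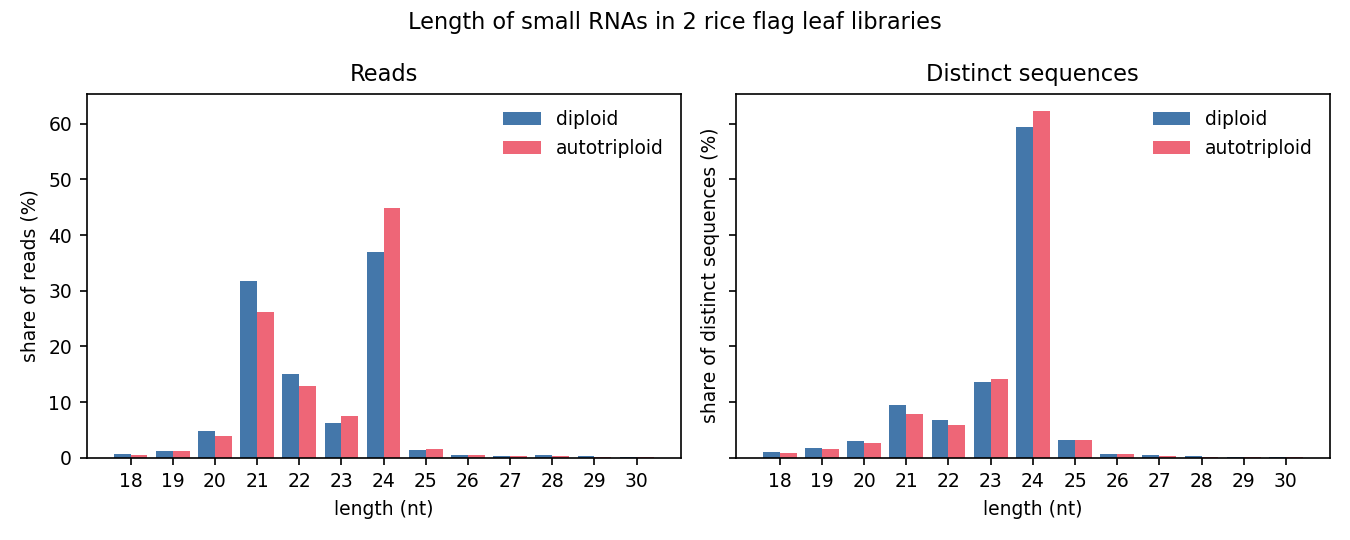
Share of reads (left) and of distinct sequences (right) at each length from 18 to 30 nt, in percent of each library, with 1 bar per library and no error bars because the counting intervals are narrower than the bar outlines. The 24-nt bar is taller in the autotriploid library (44.9% against 37.0% of reads) and the 21-nt bar is shorter (26.2% against 31.8%).

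The autotriploid library also held more kinds of small RNA. With the diploid library thinned to the depth of the autotriploid one, 1965069 distinct sequences were expected, and the autotriploid library held 2298182, or 1.17 times as many. At this equal total depth, distinct 24-nt sequences were 1.22 times and 23-nt sequences 1.22 times as many. Those of 20, 21 and 22 nt were 1.03, 0.97 and 1.04 times as many. Shares of reads had ratios of 1.21 at 24 nt and 1.18 at 23 nt, but 0.81, 0.83 and 0.86 at 20, 21 and 22 nt. The ratios of distinct sequences thus depend on the reads in each class and do not compare diversity within a class. Equal numbers of reads within a class were compared for 24 nt only. Counting only sequences with 2 or more reads, the ratio was 1.15 over all lengths and 0.83 at 21 nt.

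The 5′ base of a plant small RNA helps to decide which Argonaute protein binds it. In 21-nt reads U led in both libraries, with 83.4% (83.39 to 83.49%) in the diploid and 84.3% (84.21 to 84.33%) in the autotriploid library. In 24-nt reads A led, with 60.4% (60.38 to 60.50%) in the diploid and 59.1% (59.07 to 59.18%) in the autotriploid library. Reads of 24 nt that began with C made up 6.81% of that class in the diploid and 8.34% in the autotriploid library. Among 22-nt reads those that began with A were 14.1% and 11.3%. These included the 22-nt reads of the miRNA miR1432, 40076 in the diploid and 10471 in the autotriploid library. Among distinct 22-nt sequences A began 40.9% and 37.0%.

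The second comparison concerned known miRNA families. Of the 39 listed families, 35 gave at least 1 read, and 33 reached 10 reads in a library. Assigned reads were 30.2% of the diploid and 27.1% of the autotriploid library. The most abundant family was miR167, which targets auxin response factor genes, with 143102 RPM in the diploid and 143114 in the autotriploid library. Its ratio was 1.20 when scaled to reads of 20 to 22 nt and 0.95 with the TMM-type factor. Next came miR168, which targets AGO1, with 95346 and 83863 RPM. At the 2-fold limit 3 families were lower in the autotriploid library and 0 were higher. Over all 33 families 7 were lower and 9 higher under all 3 scalings, and 17 had no direction that held under all of them.

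The families called lower were miR1432, miR1850 and miR530, all from the list of families known in grasses. miR1432 had 7069 RPM in the diploid library (95% interval 7008 to 7131) and 2180 (2144 to 2218) in the autotriploid library, a ratio of 0.31 (0.30 to 0.31). miR1850 had 44.6 and 15.5 RPM, a ratio of 0.35 (0.27 to 0.44). miR530 had 187 and 67.0 RPM, a ratio of 0.36 (0.32 to 0.40). These families stayed below 0.5 under each of the 3 scalings. With only reads identical to a listed sequence counted, miR530 had 4 and 0 reads and was not compared, because the listed sequence has 20 bases and most reads of the family, 1288 and 408, had 21. In the same list miR1425, whose targets encode pentatricopeptide repeat proteins, was lower at a ratio of 0.70 (0.64 to 0.77). The fifth member, miR444, which targets MADS-box genes, stood at 0.95 and moved to 1.14 when scaled to reads of 20 to 22 nt. The median log2 ratio of this list was -1.48, at percentile 0.07 of random lists, whose median was -0.30.

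Among the 13 families of the development list, 11 were compared, of which 5 were higher and 2 lower under all 3 scalings. miR171, which targets GRAS genes of the scarecrow-like type, had 29.5 RPM in the diploid and 53.2 in the autotriploid library, a ratio of 1.80 (1.51 to 2.15). miR164, which targets NAC genes, had 443 and 709 RPM, a ratio of 1.60 (1.53 to 1.67). miR396, which targets growth-regulating factor genes, stood at 1.19 (1.14 to 1.25), miR172, which targets AP2-type genes, at 1.11 (1.07 to 1.14), and miR166, which targets class III HD-ZIP genes, at 1.08 (1.06 to 1.09). Lower were miR535, at 0.55 (0.54 to 0.56), and miR156, at 0.75 (0.74 to 0.75), both of which target SPL genes. Most miR156 reads began at another base than the listed start. With starts up to 3 nt away included, miR156 had 535952 and 259289 reads and a ratio of 0.555 (0.552 to 0.558). With starts up to 3 nt away miR166 lost its direction, with a TMM-type ratio of 1.001 (0.990 to 1.012), and miR529 was higher on 2 and 12 reads. The remaining families of the list, miR159, miR160, miR167 and miR394, had no common direction. The median log2 ratio of the list was 0.11, at percentile 99.6 of random lists, whose median was -0.31.

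Of the 7 families in the nutrient list, 6 were compared. miR827, which targets genes of SPX-domain phosphate transporters, was higher, with 121 RPM in the diploid and 220 in the autotriploid library, a ratio of 1.83 (1.68 to 1.99). miR528, which targets genes of copper proteins, was lower, with 16988 and 9528 RPM, a ratio of 0.56 (0.56 to 0.57). miR397, miR398, miR399 and miR408 had between 14 and 97 reads per library and no common direction. The list's median log2 ratio was -0.29, at percentile 53.3 of random lists. For miR397 the listed start carried only 45 and 41 reads. With starts up to 3 nt away included, it had 3366 and 1340 reads and a ratio of 0.46 (0.43 to 0.49).

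In the list of families tied to the silencing pathway, 2 of 5 were higher and none lower under all 3 scalings. These were miR390, which triggers tasiRNA production from TAS3 transcripts, at 1.52 (1.09 to 2.13), and tasiR-ARF, the product of that pathway, at 1.55 (1.24 to 1.94). miR390 rested on 65 and 86 reads and tasiR-ARF on 145 and 196 reads. With starts up to 3 nt away, tasiR-ARF had 1539 and 1755 reads and a ratio of 1.31 (1.22 to 1.40). miR168 stood at 0.88, miR162, which targets DCL1, at 0.92, and miR820, which targets a DNA methyltransferase gene, at 1.08. miR168 and miR162 moved to 1.054 and 1.101 when scaled to reads of 20 to 22 nt. The reads counted for miR820 were mostly of 24 nt, 3614 and 3400 reads that share the first 18 nt of the listed 21-nt sequence, which itself had 0 and 3 reads. The list's median log2 ratio of 0.11 was the value of miR820. It lay at percentile 97.3 of random lists of 20-to-22-nt sequences and at 95.3 of lists matched on length.

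Among the 24-nt miRNAs miR1863 was higher, at 1.52 (1.36 to 1.71), and miR1862, miR1873 and miR1876 had no common direction. The median log2 ratio of the 4 was 0.23, at percentile 78.5 of random lists of unlisted 23-to-24-nt sequences, whose median was 0.09. Against the planned lists of 20-to-22-nt sequences, which differ from it in length, it was 98.7. In the stress list miR169, which targets NF-YA genes, stood at 0.81 and miR393, which targets auxin receptor genes, at 1.09, neither with a common direction. The list's median was -0.09 on the log2 scale, at percentile 79.3, and turned to 0.17 when scaled to reads of 20 to 22 nt. The panicle markers miR2118 and miR2275 gave 0 reads in both libraries, which by the limit of 3 reads allows up to 0.422 RPM in the diploid and 0.484 in the autotriploid library. miR395 and miR1883 also had 0 reads in both at the listed start, but 8 and 6 and 2 and 0 reads with starts up to 3 nt away. miR319 had 1 and 0 reads.

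Taken as 1 list, the 33 families had a median log2 ratio of -0.07, which lay at percentile 99.8 of random lists with a median of -0.31 and at 98.3 of lists matched on length, with a median of -0.23. That median changed sign with the scaling and was 0.19 when scaled to reads of 20 to 22 nt. Under this scaling miR171 and miR827 passed the 2-fold limit as higher, at 2.16 and 2.19. Under the TMM-type factor 0 families were higher and 3 lower. The random lists could hold forms of the listed families with shifted starts, so these percentiles do not compare the families only with other RNA.

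**Figure D2:**
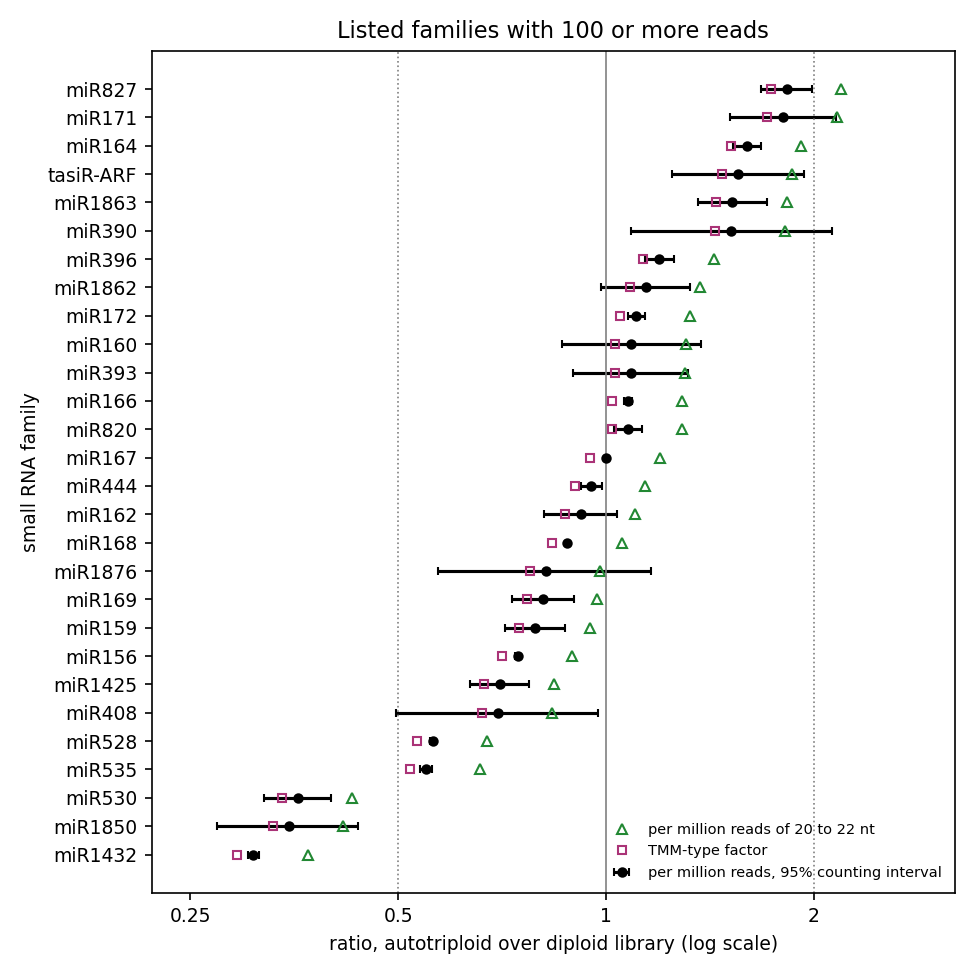
Ratio of the autotriploid to the diploid library (log axis) for the 28 listed families with 100 or more reads, ordered by ratio. Black points with 95% counting intervals are RPM ratios, triangles those scaled to reads of 20 to 22 nt and squares with the TMM-type factor; dotted lines mark ratios of 0.5 and 2, and miR1432, miR1850 and miR530 lie below 0.5 with every symbol.

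Members of a family did not always differ in the same direction, as seen in members picked after their values were known. In miR167 the 21-nt sequence TGAAGCTGCCAGCATGATCTA had 35566 RPM in the diploid and 47505 in the autotriploid library, a ratio of 1.34 (1.33 to 1.34). All miR167 reads of 22 nt together stood at 0.87 (0.87 to 0.87), and at 1.04 when scaled to reads of 20 to 22 nt. In miR164 the member TGGAGAAGCAGGGCACGTGCA stood at 1.71 (1.63 to 1.80), whereas TGGAGAAGCAGGGCACGTGAG, with 227 and 51 reads, stood at 0.26 (0.19 to 0.35). In miR169 the member CAGCCAAGGATGACTTGCCGA stood at 0.32 (0.23 to 0.43) with 200 and 56 reads, and CAGCCAAGGATGACTTGCCGG at 0.91 (0.80 to 1.02) and 1.09 when scaled to reads of 20 to 22 nt.

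Complementary strands of miRNA duplexes were counted only where identical to a listed star sequence, and these were not checked against a reference, so a count of 0 does not show that a strand was absent. Of 7 listed star sequences 4 were found, and the most abundant was that of miR168, CCCGCCTTGCACCAAGTGAAT, with 73 and 50 reads and a ratio of 0.79 (0.54 to 1.14). The miR166 star GGAATGTTGTCTGGCTCGAGG had 51 and 54 reads, a ratio of 1.21 (0.81 to 1.82). Neither difference was detectable at this depth.

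The third comparison took all distinct sequences with 100 or more reads over both libraries, of which there were 4449. At the 2-fold limit 129 were higher and 351 lower in the autotriploid library. The directions split by length. Of 2490 sequences of 24 nt, 106 were higher and 27 lower, with a median log2 ratio of 0.13. Of 1395 sequences of 20 to 22 nt, 15 were higher and 233 lower, with a median of -0.36. Of 229 sequences of 25 to 30 nt, 1 was higher and 57 lower, with a median of -0.53. The overall split depended on the scaling, with 282 higher and 204 lower when scaled to reads of 20 to 22 nt, and 96 higher and 414 lower with the TMM-type factor. Many of these sequences overlapped: joined wherever they shared 16 bases on either strand, the 129 higher sequences formed 110 groups and the 351 lower ones 189 groups.

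**Figure D3:**
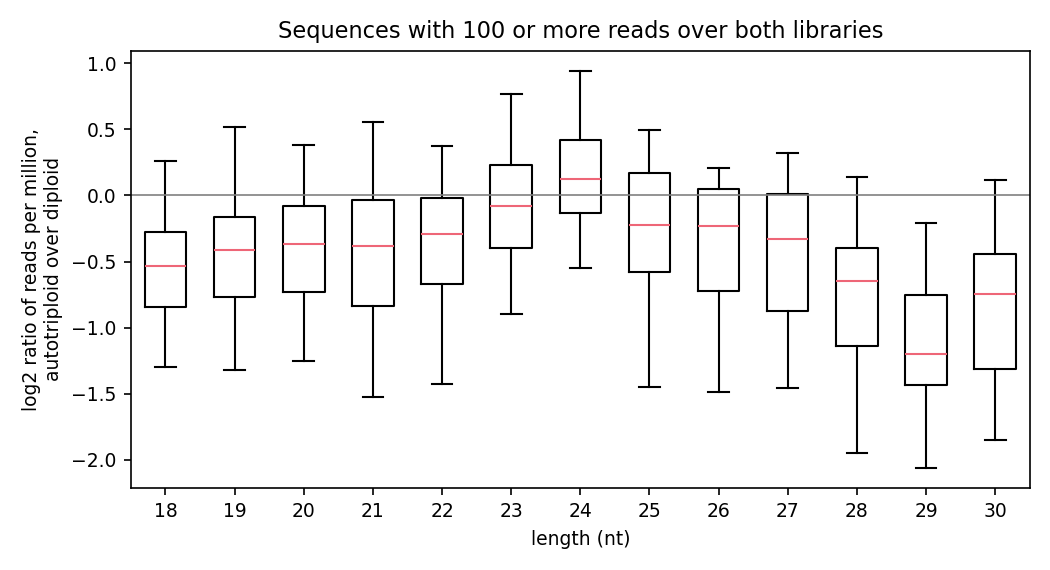
Log2 ratio of RPM, autotriploid over diploid, for the 4449 sequences with 100 or more reads, by length in nt. Boxes span the quartiles with the median in red and whiskers reach from the 5th to the 95th percentile; the 24-nt median is 0.13, and the medians of all other lengths lie below 0, down to -1.20 at 29 nt.

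Among unlisted sequences the most abundant was TTGACAGAAGAGAGTGAGCAC, which is miR156 with 1 more base at the 5′ end. It had 49428 RPM in the diploid and 23065 in the autotriploid library, a ratio of 0.47 (0.46 to 0.47), and 0.56 when scaled to reads of 20 to 22 nt. A second miR156 form with 2 more 5′ bases, ATTGACAGAAGAGAGTGAGCAC, had the lowest ratio of all unlisted sequences with 1000 or more reads, 0.27 (0.24 to 0.31). Forms of miR1432 that start 1 base later, TCAGGAGAGATGACACCGACA and TCAGGAGAGATGACACCGAC, stood at 0.30 (0.28 to 0.32) and 0.30 (0.29 to 0.32). Also abundant were the miR166 form TTCGGACCAGGCTTCATTCCC at 0.92 (0.90 to 0.95) and the miR167 form GAAGCTGCCAGCATGATCTGA at 0.91 (0.88 to 0.94). Both of these lay above 1 when scaled to reads of 20 to 22 nt, at 1.11 and 1.09.

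Sequences outside the listed families included TGGGAGTTCATGAAGCGGTCA, with 9916 and 6560 RPM and a ratio of 0.66 (0.65 to 0.67), and AAGGCATGAAGCAATGTAACA, at 0.63 (0.62 to 0.64). The 28-nt sequence GCGCCTGTAGCTCAGTGGATAGAGCTTT stood at 0.76 (0.73 to 0.78). TGAGGAATCACTAGTAGTCGT at 0.85, TAGAGCGGTGTTATTGCGGACA at 1.02 and TAAGCATTTTGAAAGGCTGGA at 1.01 had no direction common to all scalings. The lowest ratios further included CAGTTACTAATTCATGATCTGG, at 0.31 (0.27 to 0.36), and the 29-nt ATATCGGGTAGGTTGTGGTATTTCATTTC, at 0.32 (0.29 to 0.34).

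The highest ratio among unlisted sequences with 1000 or more reads was that of the 20-nt AAACGGCGAGACCATGGTGC, with 69.8 RPM in the diploid and 187 in the autotriploid library, a ratio of 2.68 (2.41 to 2.98). The next highest was TCGCTTGGTGCCGATCGGGAC, at 1.74 (1.60 to 1.89), which lies 1 mismatch from miR168. The other 3 were 24 nt long. TGCTGAATTAGACCTAGTGGGCAT stood at 1.73 (1.61 to 1.86), AGAAAGAGATGACGACGCGTCGGA at 1.70 (1.502 to 1.925) and ACGAACGGTTAAAGTTGGACGCGG at 1.59 (1.54 to 1.65). The last was the most abundant unlisted 24-nt sequence, with 855 and 1362 RPM.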

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

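No paired analysis was possible because each ploidy has 1 library, and for the same reason none could be left out. Alternatives that need a genome match were not run, nor were results by genome class, window or chromosome. Starts shifted by up to 3 nt and the removal of listed families were chosen after seeing the data. The 24-nt difference of 7.94 percentage points became 2.99 among distinct sequences, 6.20 without the 20 most abundant sequences and 6.39 without listed families. The 21-nt difference of -5.54 became -5.96 within 20 to 25 nt, -1.64 among distinct sequences, -3.55 without the 20 most abundant sequences and -4.12 without listed families. The excess of distinct sequences went from 1.17 to 1.15 times when single reads were dropped. Among distinct sequences the 5′ U difference at 21 nt went from 0.83 to 0.70 percentage points and the 5′ A difference at 24 nt from -1.31 to -1.41. The 0 families called higher became 2 relative to reads of 20 to 22 nt (miR171 and miR827) and 1 both without a read minimum and with shifted starts (miR529, on 2 and 9 or 2 and 12 reads). The 3 called lower ranged from 2 to 4 over all alternatives, with miR397 added by shifted starts and miR530 lost with identical sequences only, since its listed form, a base shorter than most of its reads, had 4 and 0 reads. The families' median log2 ratio of -0.07 turned to 0.19 relative to reads of 20 to 22 nt and 0.00012 with a minimum of 100 reads. The 129 higher and 351 lower sequences became 282 and 204 relative to reads of 20 to 22 nt, 1 and 31 with a minimum of 1000 reads, and 2129 and 2189 with a minimum of 20 reads, where more sequences were compared. For the moves with scaling, the added shift of 0.26 on the log2 scale is the cause by construction; other causes were not tested. For single named families and sequences, 81 alternative ratios stayed within the counting interval, 67 left it and 0 of the called ones turned. With shifted starts 9 families were higher and 8 lower under all 3 scalings (miR166 lost, miR529 and miR397 gained), and with identical sequences only 10 and 6 (miR167 gained, miR530 lost). Depth limits families under 100 reads, such as miR394, miR398 and miR399, whose intervals span 1.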

Other observations

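All tests in this part were chosen after the results were seen, except the test on unlisted sequences with the same start.

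Unlisted reads with a sequence motif of transfer RNA were less abundant in the autotriploid library. Unlisted reads with the A-box motif, the internal promoter sequence near the 5′ end of tRNA genes, stood at 20960 RPM in the diploid and 15510 in the autotriploid library, a ratio of 0.740 (0.734 to 0.746). That ratio was 0.887 relative to reads of 20 to 22 nt and 0.702 with the TMM-type factor. By length it was 0.690 at 18 to 22 nt and 0.681 at 26 to 30 nt, but 0.967 at 23 to 25 nt, where it turned to 1.16 relative to reads of 20 to 22 nt. The motif read backwards, as a background, stood at 0.982 over all lengths, 0.813 at 18 to 22 nt, 1.11 at 23 to 25 nt and 0.852 at 26 to 30 nt. Among reads of 26 to 30 nt the motif was found in 26.3% of diploid and 23.4% of autotriploid reads, and the reversed motif in 0.433% and 0.482%. The miR168 sequence also fits the motif. Of miR168 and the reads 1 mismatch away from it, the latter were 4.70% in the diploid and 4.75% in the autotriploid library. Some of them counted as unlisted reads with the motif, and how many was not measured. The ratios at 18 to 22 nt and over all lengths therefore do not stand for transfer RNA alone, and the reversed motif does not correct for this.

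The higher share of 24-nt reads in the autotriploid library was set against 2 technical explanations. A few abundant miRNAs taking fewer reads cannot be the whole cause, because a difference of 6.39 percentage points was left without the listed families. Size selection that favoured longer RNA would shift long against short forms of the same RNA: 23-to-24-nt forms shifted against 20-to-22-nt forms by a median of 0.17 on the log2 scale (bootstrap 0.04 to 0.39) within 10 families, and by 0.30 (0.25 to 0.36) within 436 sets of unlisted reads with the same first 18 nt, upward in 334 of them. Sets whose starts overlap were not joined, so the interval for the 436 sets may be too narrow. The shift over all reads was 0.54, and both intervals span the 0.27 taken as the divide, so size selection stays open for at least part of the difference. Reads of 26 to 30 nt had a ratio of 0.766 (0.759 to 0.772), so the rise did not extend to the longest reads. Ploidy stays open too and was not tested, since it cannot be separated from the library.

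Reads of miR156 at shifted starts had lower ratios than those at the listed start (0.745), whether they began earlier (0.467, 0.414 and 0.525 with 1, 2 and 3 more 5′ bases) or later (0.621 and 0.463 with 1 and 2 fewer). The tests covered the most abundant of these, with 1 more base, which differed from the listed start by -0.67 on the log2 scale. A shift of 5′ ends common to all families had a median of 0.077 (bootstrap 0.029 to 0.26) in 9 other families, most with few such reads, and was -0.22 in miR166, the best measured of them with 17095 and 13822 reads, which argues against it as the whole cause only. A bias of 21-nt against 20-nt reads had a median of -0.15 (-0.33 to 0.20) in 8 other families and was -0.33 (counting interval -0.52 to -0.15) in miR156 itself at the listed start, so it is too small for the whole difference but may account for part of it. Different precursors remain a hypothesis that was not tested, because reads were not matched to precursors here.

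The autotriploid library held 1.17 times as many distinct sequences at equal depth. Sequencing error was weighed through reads 1 mismatch away from the 4 most abundant sequences. The share of such reads had a median ratio of 1.002 (range 0.937 to 1.010) between libraries. This median replaced a ratio pooled over the 4 sequences after that ratio, 1.048, had been seen, and the pooled value lay just below the bound set against sequencing error. A larger share of reads in the diverse 24-nt class is consistent with most of the 24-nt excess, since distinct 24-nt sequences were 1.22 times as many at equal total depth and 1.051 times as many at equal numbers of 24-nt reads. What is left is 22.8% of the 24-nt excess, below the 25% taken as the divide, a reference chosen after the value was seen, and ploidy was not tested.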
